A study of Homo sapiens with 14 samples.

How the data were processed

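The data are one table of expression array values for 14 human samples, 6 of platelets from patients with essential thrombocythemia (ET), 5 of normal platelets and 3 of normal leukocytes. Groups were taken from the sample labels. The table holds intensity values on a linear scale, as deposited by the authors, for 22277 probe sets. The software that made the values, and its scaling target, are not given in the sources used here. The 2% trimmed mean of each column lay between 249.1 and 250.2, so the arrays had been scaled to a common level before deposit and were used without further normalization. Scaling of that kind cannot show a change in the total amount of RNA, and a trimmed mean leaves out the brightest probe sets. The 10 brightest probe sets held 9.30% to 18.1% of the summed intensity in normal platelets, 2.34% to 13.1% in ET platelets and 1.96% to 2.28% in leukocytes. Whether they weigh on an array's other values was not tested. No detection calls were used here. For arrays, precision is limited by the number of arrays, and there is no read depth. No pair of samples held more than 0.341% equal values, so none was taken for a repeat deposit. There were 0 columns of per-sample values left unused.

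Of the probe sets, 19071 had 1 gene symbol in the platform annotation, 1043 had several, 2107 had none, and 62 were controls (some controls also carry a symbol). Symbols were updated through gene identifiers for 19059 of them with a reference table of assembly GRCh38.p14, used for names only, since the build behind the array is not stated, so no coordinates are given. Probe sets for XIST and Y-linked genes, 52 in all, were left out of every step, which left 19034 probe sets of 11939 genes.

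Values were transformed as log2(value + 32). A fold on this scale understates the change of dim genes. In each comparison a probe set was kept where it reached its own array's median in at least as many samples as the smaller group holds, and each gene was represented by its kept probe set with the highest mean. This left 7722 genes for ET against normal platelets, 9040 for normal platelets against leukocytes and 8993 for ET platelets against leukocytes. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with only the samples of the groups compared in each fit, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels state no test. Errors of log2 differences are standard errors, and errors of intensities are SDs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

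The choice of groups, tests, gene lists and most alternatives was made before the data were examined. The 25 gene lists cover platelet adhesion receptors, alpha granule and secreted proteins, activation receptors and signalling, cytoskeleton, steroid hormone metabolism, eicosanoid synthesis, JAK-STAT target genes, interferon-induced genes, ribosomal proteins, oxidative phosphorylation, proteasome, translation factors, immediate early and stress genes, BCL2 family and caspases, markers of leukocytes in general, of neutrophils and their precursors, of monocytes, T cells, B cells and NK cells, MHC class II, erythroid markers and genes of dividing cells. The result of 1 further list among the 25 is not reported here, though it counts in the numbers of lists tested. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list's genes move one way without comparing them with other genes. Mean levels of the marker lists and of control measures were compared by two-sided exact permutation tests over all 462 splits of the 11 platelet samples.

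The genes named follow a fixed rule. For ET against normal platelets and for normal platelets against leukocytes these are the 10 genes with the largest difference in each direction among those past the threshold whose groups do not overlap, up to 3 members with the smallest adjusted p of each list, and 17 genes fixed beforehand, among them the hydroxysteroid dehydrogenases HSD17B3, HSD17B1, HSD17B2, HSD17B11 and HSD17B12. Genes named outside the rule are said to be so. For ET platelets against leukocytes only counts and lists are given.

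The tests were tried on simulated data made from the real genes' means and spread. For ET against normal platelets, 1 of 50 genes planted with a log2 change of 1 was recovered, 29 of 50 with a change of 2, and 50 of 50 with a change of 3 and of 4, with 4 false calls among 134. For normal platelets against leukocytes the recovered numbers were 3, 34, 44 and 46 of 50, and for ET platelets against leukocytes 3, 30, 46 and 49 of 50. The simulated genes varied independently of each other, so variation shared between genes was not covered and real false calls may be more frequent.

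Alternatives were other pseudocounts (8 and 128) or a floor of 32, quantile normalization, centring on the median, no filter or a filter at the 75th percentile, all probe sets of a gene or their mean, a variance trend, array weights, all 14 samples in one fit, the pan-leukocyte marker level as a covariate, leaving out genes at least 4-fold higher in leukocytes, and leaving out each sample in turn. Added after seeing the data were the level of the hybridization controls as a covariate and as a block, the ratio of 3' to 5' control probe sets as a covariate, and leaving out samples that stand apart. All covariates and the block by control level were tried for ET against normal platelets only.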

Results

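Transcript levels were measured on an expression array of 22277 probe sets in 14 human blood cell samples. They comprised 6 samples of platelets from patients with essential thrombocythemia (ET, a chronic disorder in which the bone marrow releases too many platelets), 5 samples of normal platelets and 3 samples of normal leukocytes, the white cells of the blood. Platelets have no nucleus and carry RNA inherited from the megakaryocytes that shed them. Each array had been brought to a common scale before deposit, with trimmed mean intensities between 249.1 and 250.2, while median intensities ran from 49.3 to 115.6 in ET platelets, from 58.6 to 136.4 in normal platelets and from 88.3 to 91.9 in leukocytes. The leukocyte samples resembled each other closely, with Spearman correlations of 0.952 to 0.957 across probe sets. Pairs of ET platelet samples had a median correlation of 0.693, pairs of normal platelet samples 0.698 and mixed platelet pairs 0.612. The number of arrays limits the precision of every value. As no source used here says how the samples of a group relate to separate donors or preparations, p-values measure the spread between these samples, part of which may be technical.

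The first comparison asks which transcripts differ between ET platelets and normal platelets. The gene with the largest rise was HPSE, which encodes heparanase, an enzyme that cleaves heparan sulfate, with a mean intensity of 6045 in ET platelets and 116.9 in normal platelets. It was 29.6-fold higher in ET platelets (log2 difference 4.89 ± 0.59 SE, n = 6 and 5, adjusted p = 1.43e-05). The enzymes of steroid hormone metabolism HSD17B3 and HSD17B12 moved in opposite directions. HSD17B3, which converts androstenedione to testosterone, fell from 2019 ± 961 in normal platelets to 261 ± 195 in ET platelets (SD, n = 5 and 6), a log2 difference of -2.91 ± 0.50 SE (adjusted p = 0.000572). HSD17B12, which takes part in fatty acid elongation and can act on estrogens, had an intensity of 189 ± 78.1 in normal platelets and 2411 ± 1507 in ET platelets, a log2 difference of 3.30 ± 0.47 SE (adjusted p = 7.63e-05). For both genes every ET sample lay on one side of every normal sample, and in leukocytes their intensities were 70.6 ± 24.5 and 292.5 ± 25.7 (SD, n = 3).

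**Figure D1:**
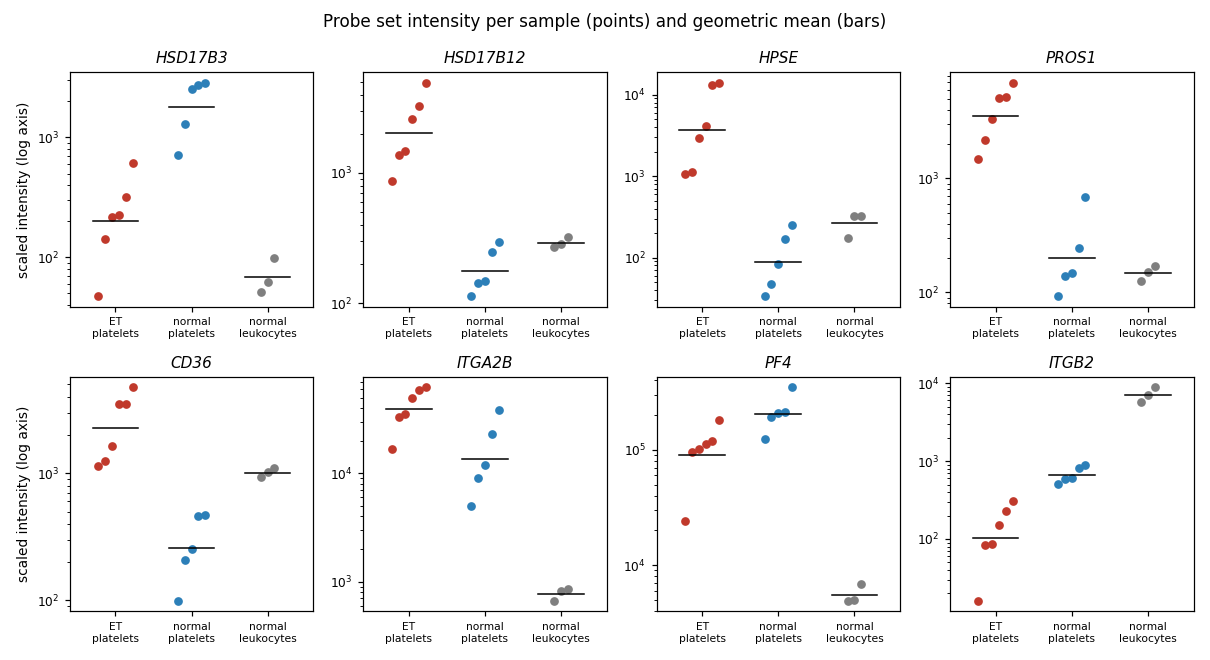
Probe set intensity (log axis, arbitrary units as deposited) of 8 genes in 6 ET platelet, 5 normal platelet and 3 normal leukocyte samples; each point is 1 sample and each bar the geometric mean. HSD17B3 lies lower and HSD17B12, HPSE, PROS1 and CD36 lie higher in each ET sample than in every normal platelet sample, while the groups overlap for ITGA2B and PF4.

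In all, 910 of 7722 genes tested (11.8%) differed between ET and normal platelets by limma at an adjusted p under 0.05, of which 435 were higher and 475 lower in ET platelets. Counts of list members are to be read against that share. The groups did not overlap in 188 of the higher and 183 of the lower genes, where chance gives 0.433% of all genes for both directions together. The median log2 difference of all tested genes was -0.30, so differences are to be read against that shift. With each array centred on its median the calls split into 519 higher and 206 lower genes, and with quantile normalization into 535 and 412.

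Technical measures were compared between the platelet groups as well. The bacterial transcripts added at hybridization read 13.19 ± 1.28 (log2, SD, n = 6) in ET platelets, 14.58 ± 0.54 (n = 5) in normal platelets and 11.02 ± 0.27 (n = 3) in leukocytes, with p = 0.0368 for the platelet groups by a two-sided exact permutation test (0.092 after adjustment over 5 measures). The median Spearman correlation of a sample to the leukocyte samples was 0.449 ± 0.081 in ET platelets and 0.326 ± 0.061 in normal platelets (SD, n = 6 and 5, exact p = 0.026, adjusted 0.092). The 18S rRNA control level was 8.52 ± 2.32 and 10.92 ± 1.16 on the log2 scale (SD, n = 6 and 5, exact p = 0.0671, adjusted 0.112). The log2 ratio of 3' to 5' control probe sets was 0.89 ± 0.70 and 1.21 ± 0.68 (exact p = 0.459) and the array median differed by -0.33 (exact p = 0.316). With the hybridization control level as a covariate, an alternative chosen after seeing the data, 19 genes were past the threshold, 15 higher and 4 lower, of which 18 were among the 910. With the 5 samples of highest control level set against the other 6 as a block, 46 genes were, 34 higher and 12 lower, of which 44 were among the 910. HPSE, PROS1, P4HB, LAPTM4B, FCGR2C, NDFIP1, HBQ1, HSD17B12, HSD17B3, SLC35F6, ZNF205 and ZNHIT2 were among the 19, and the other calls named for this comparison were lost. All 435 higher and 475 lower calls kept their sign under the covariate. Their median log2 difference went from 1.82 to 1.48 in the higher genes and from -1.64 to -1.36 in the lower genes, and the standard errors grew by a median factor of 1.20. Leaving out single samples gave between 447 and 1362 genes, and leaving out the 3 samples that stand apart from their group or lie nearest to the leukocytes gave 341.

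**Figure D2:**
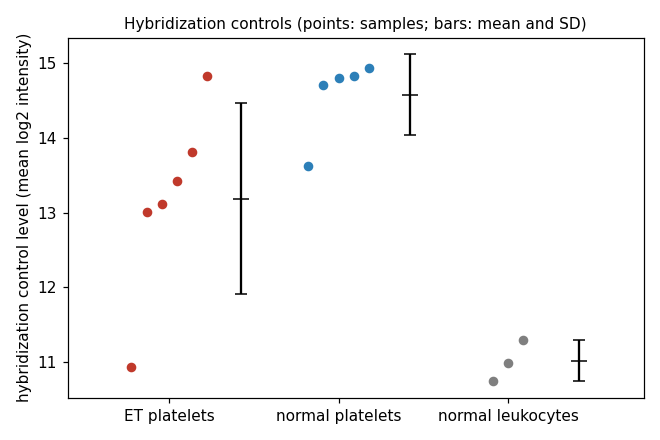
Hybridization control level (mean log2 intensity of 9 probe sets for bacterial transcripts) per sample in the 3 groups; points are samples, and bars to the right show mean and SD. The level was 13.19 ± 1.28 in ET platelets, 14.58 ± 0.54 in normal platelets and 11.02 ± 0.27 in leukocytes.

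Next to HPSE, the largest rises among genes whose groups did not overlap were those of P4HB, CCNG1 and PCTP. P4HB, a protein disulfide isomerase of the endoplasmic reticulum, was 19.5-fold higher (log2 difference 4.29 ± 0.58 SE, adjusted p = 6.15e-05). CCNG1, encoding cyclin G, was 16.6-fold higher, and PCTP, a phosphatidylcholine transfer protein, 18.3-fold higher, although its normal platelet intensity of 27.7 lay near the added constant of 32. PROS1, encoding the anticoagulant protein S, was 15.0-fold higher. LAPTM4B, FCGR2C, NDFIP1, XK and ITFG1 were 14.2-, 12.2-, 12.1-, 11.5- and 10.6-fold higher. FCGR2C shares most of its sequence with other Fc gamma receptor genes, so which of them its probe set read is uncertain. Besides HSD17B3, the largest falls were those of ZNF205 (7.55-fold lower, log2 difference -2.92 ± 0.44 SE, adjusted p = 0.000142) and ZNHIT2 (6.80-fold lower). SLC35F6, TET3, REEP2, SOX4, SCNN1A, LILRB3 and GLI1 were between 6.22- and 5.77-fold lower.

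Among gene groups fixed before the data were examined, the platelet adhesion receptors had the smallest p by camera at the preset correlation, though not with an estimated one. Of 21 tested, 8 rose and none fell over all genes tested, and 10 rose when adjusted over the list alone. The median log2 difference was 1.15, which is 1.45 above that of all genes (camera adjusted p = 1.94e-08, and adjusted p = 0.173 with an estimated correlation). CD36, a scavenger and thrombospondin receptor, was 7.83-fold higher (log2 difference 2.97 ± 0.49 SE, adjusted p = 0.000289). PECAM1 was 5.72-fold higher, SELP (P-selectin) 4.37-fold, and ITGA2B and ITGB3, the subunits of the fibrinogen receptor, 2.85- and 3.14-fold. The calls of ITGA2B and ITGB3 lay just past the threshold (adjusted p = 0.0458 and 0.0494) and were lost in 14 and 17 of 28 alternatives (adjusted p from 0.0127 to 0.556 and from 0.00291 to 0.817). Under the hybridization control covariate the calls of all 5 genes were lost. The log2 difference was then 2.33 ± 0.57 SE for CD36, with an adjusted p of 0.0615 (2.35e-05 to 0.0615 over its 28 alternatives). It went from 2.52 ± 0.48 to 1.99 ± 0.57 for PECAM1, from 2.13 ± 0.47 to 1.52 ± 0.54 for SELP, from 1.65 ± 0.56 to 0.88 ± 0.66 for ITGB3 and from 1.51 ± 0.50 to 1.66 ± 0.63 SE for ITGA2B, whose difference did not shrink while its error grew. Among 36 activation receptors and signalling genes 4 rose and 1 fell (7 and 1 adjusted over the list alone), with camera adjusted p = 0.00536 and adjusted p = 0.221 with an estimated correlation. They included FCGR2A, an Fc receptor (7.30-fold higher), and P2RX1, an ATP-gated channel (3.88-fold higher). In the cytoskeleton list 4 of 30 rose and none fell (4 and 1 adjusted over the list alone), with DIAPH1 4.36-fold, GSN 3.99-fold and CALD1 3.89-fold higher (camera adjusted p = 0.00659, and adjusted p = 0.563 with an estimated correlation). The cytoskeleton list lost its call in 5 of 16 alternatives, with a median log2 difference from 0.07 to 0.58, and the activation receptor list in 2 of 16. Fry was among these for both lists (adjusted p = 0.352 and 0.0779).

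The list of alpha granule and secreted proteins did not pass the threshold in the main test and passed in 6 of 16 alternatives (adjusted p from 0.0182 to 0.437). Of 35 tested, 6 rose and none fell, both over all genes and adjusted over the list alone, the median log2 difference was -0.10 and the mean 0.28 (camera adjusted p = 0.0622, and 0.437 with an estimated correlation). EGF was 9.07-fold higher and VWF (von Willebrand factor) 4.26-fold higher. The abundant granule chemokines PF4 and PPBP had means of 105990 and 97512 in ET platelets against 217622 and 218323 in normal platelets, log2 differences of -1.18 ± 0.48 and -1.33 ± 0.50 SE that did not pass the threshold (adjusted p = 0.0999 and 0.0739) but did so in 1 and 4 of 28 alternatives. In the proteasome list 6 of 27 genes rose and none fell, over all genes and adjusted over the list alone, among them PSMB8 (5.03-fold), PSMA7 (4.71-fold) and PSMD11 (3.23-fold), with camera adjusted p = 0.00336 and adjusted p = 0.221 with an estimated correlation. In the oxidative phosphorylation list 2 of 55 genes rose and 1 fell, again by both adjustments, with NDUFA8 4.21-fold higher and ATP5MC1 2.87-fold lower (camera adjusted p = 0.00536, and adjusted p = 0.501 with an estimated correlation). The list's call was lost in 4 of 16 alternatives, among them fry (adjusted p = 0.265), and that of ATP5MC1 in 6 of 27. Of cytosolic ribosomal protein genes none of 52 rose and 7 fell, by both adjustments, including RPS6 (4.29-fold lower), RPL3 (3.78-fold lower) and RPL23A (3.51-fold lower), with a median log2 difference of -0.83 (camera adjusted p = 0.00029, and adjusted p = 0.618 with an estimated correlation). The list's call was lost in both alternatives that change the test, the estimated correlation (0.656 for this list) and fry (adjusted p = 0.156). It was kept in the others of 16, which hold the preset correlation. The call of RPL23A was lost in 8 of 28. Such genes have many near-identical pseudogenes, so their probe sets may read more than 1 transcript.

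Some markers of other blood cells differed between the platelet groups. Of 14 neutrophil markers tested none rose and 5 fell, by both adjustments (camera adjusted p = 0.00659, and adjusted p = 0.221 with an estimated correlation). S100A9 was 3.74-fold lower and S100A8, encoding its partner in the protein calprotectin, 3.48-fold lower, a call (adjusted p = 0.0455) that was lost in 15 of 28 alternatives with log2 differences from -2.85 to -0.54. Of 18 T cell markers none rose and 4 fell (5 adjusted over the list alone), including CD3D (4.39-fold lower) and CD5 (4.08-fold lower), with camera adjusted p = 0.0189 and adjusted p = 0.389 with an estimated correlation. Of 11 B cell markers 3 fell (4 adjusted over the list alone), among them CD79A at 3.54-fold lower (camera adjusted p = 0.0622, past the threshold in 6 of 16 alternatives). Of 16 pan-leukocyte markers 3 fell and 1 rose, by both adjustments (camera adjusted p = 0.385), with ITGB2 4.72-fold and LSP1 4.53-fold lower. In MHC class II and antigen presentation 2 of 11 fell (3 adjusted over the list alone, camera adjusted p = 0.198, past the threshold in 2 of 16 alternatives). Of 9 neutrophil precursor granule genes 2 fell (3 adjusted over the list alone, camera adjusted p = 0.0925, past the threshold in 1 of 16). No monocyte marker of 13 passed the threshold by either adjustment (camera adjusted p = 0.184), and 1 of 13 NK and cytotoxic markers, KLRB1, fell by both (camera adjusted p = 0.857). Of 25 erythroid and reticulocyte markers 4 rose and none fell (5 and none adjusted over the list alone), with XK 11.5-fold, HBQ1 6.31-fold and HBD 5.42-fold higher (camera adjusted p = 0.00536, and adjusted p = 0.173 with an estimated correlation, the call being lost in 2 of 16 alternatives).

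Averaged over each marker list per sample, the level in ET platelets minus that in normal platelets was -0.72 on the log2 scale for neutrophil markers (p = 0.00649, adjusted over 9 lists 0.039, two-sided exact permutation test). By the same exact test it was -0.78 for T cell markers (p = 0.0108, adjusted 0.039), -0.68 for MHC class II (p = 0.013, adjusted 0.039) and -0.58 for precursor granule genes (p = 0.0325, adjusted 0.0473). Monocyte and B cell markers both differed by -0.54 (exact p = 0.0368, adjusted 0.0473), and these calls were lost on leaving out some single samples. With quantile normalization they differed by -0.33 and -0.35 (exact p = 0.00433 and 0.00649). Pan-leukocyte markers differed by -0.47 (exact p = 0.0649, adjusted 0.073) and NK markers by -0.06 (exact p = 0.773), a sign that turned with quantile normalization. Erythroid markers differed by 0.37 (exact p = 0.0238, adjusted 0.0473).

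**Figure D3:**
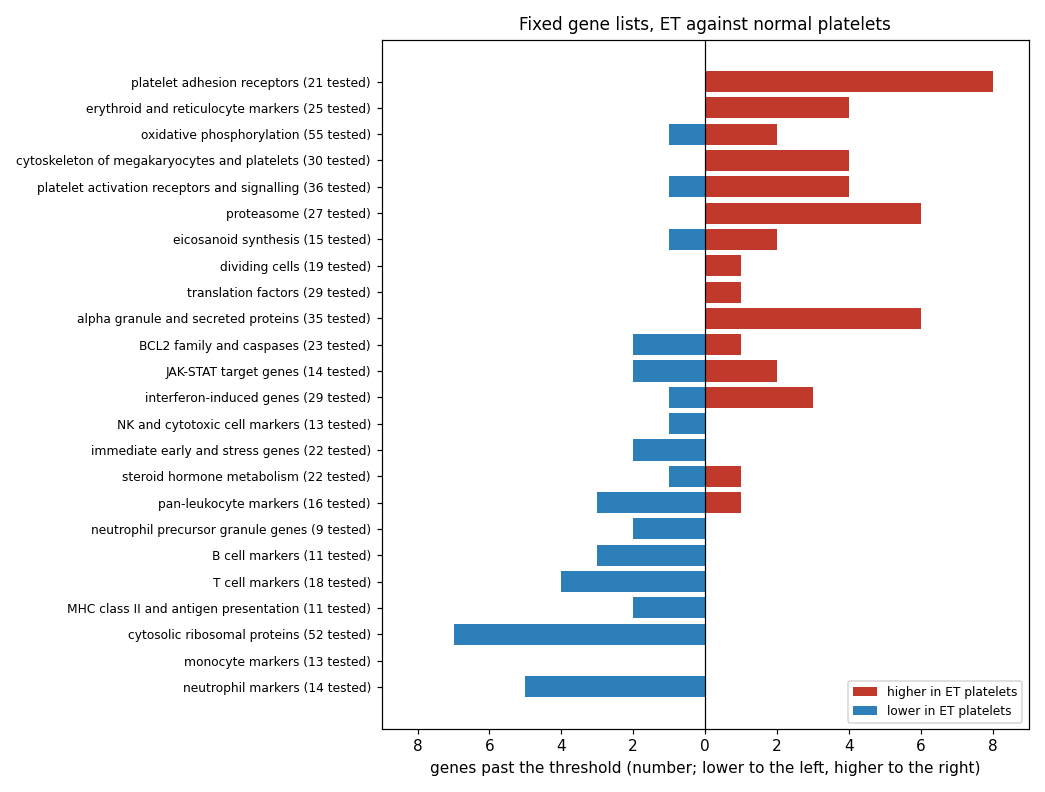
Number of genes past the threshold between ET and normal platelets in each of 24 fixed gene lists (bars to the right, higher in ET platelets; bars to the left, lower), with lists sorted by median log2 difference and the number of tested genes in brackets. The longest bars are the 8 higher adhesion receptor genes and the 7 lower ribosomal protein genes.

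Some genes of interest in ET did not pass the threshold in the main test. JAK2, the kinase mutated in many patients with the disorder, had intensities of 375 ± 177 in ET and 150 ± 140 in normal platelets (SD, n = 6 and 5, log2 difference 1.38 ± 0.49 SE, adjusted p = 0.0619). It passed in 7 of 28 alternatives, with adjusted p from 0.0238 to 0.443. The transcription factor NFE2 differed by 1.08 ± 0.52 SE (adjusted p = 0.162, past the threshold in 1 of 28 alternatives), TUBB1, the platelet beta tubulin, by 0.54 ± 0.55 SE (adjusted p = 0.521) and HBB by -0.94 ± 0.59 SE (adjusted p = 0.289). Of the remaining hydroxysteroid dehydrogenases, HSD17B1 differed by -0.63 ± 0.53 SE (adjusted p = 0.438) and HSD17B11 by 0.84 ± 0.49 SE (adjusted p = 0.248), while HSD17B2, at 39.0 ± 47.3 and 53.4 ± 63.9 (SD, n = 6 and 5), was too dim to be tested. In the steroid hormone metabolism list as a whole 1 of 22 genes rose and 1 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.603). GP1BB had no probe set annotated to that gene alone and was not analysed here.

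The second comparison asks which transcripts set normal platelets apart from leukocytes. PF4 was 37.0-fold higher in platelets (log2 difference 5.21 ± 0.41 SE, n = 5 and 3, adjusted p = 1.74e-06) and PTPRC, encoding the pan-leukocyte antigen CD45, was 53.2-fold lower (log2 difference -5.73 ± 0.48 SE, adjusted p = 2.54e-06). In the leukocyte samples PF4 and PPBP still read 5611 and 11375 on average, on arrays whose brightest probe set read 18369 to 23781. Whether these samples held platelet RNA, which would lower the folds of platelet genes, was not tested. HSD17B3 was higher in normal platelets than in leukocytes, by a log2 difference of 4.17 ± 0.49 SE (adjusted p = 1.72e-05). In all, 5718 of 9040 genes (63.3%) passed the threshold by limma, 3052 higher and 2666 lower in platelets. Counts of list members are to be read against that share. Which direction held more depended on the processing, with 3505 higher and 2281 lower after centring each array on its median, 2858 and 2896 without the normal platelet sample least like its group, and 3988 and 4506 probe sets when each was tested on its own. The groups did not overlap in 2669 of the higher and 2425 of the lower genes, where chance gives 3.57% for both directions together. The close agreement of the 3 leukocyte samples means that the common spread in the fit comes mostly from the platelets. The log2 hybridization control level was 13.6 to 14.9 in normal platelets and 10.8 to 11.3 in leukocytes. The log2 ratio of 3' to 5' control probe sets was 0.50 to 2.01 and 0.02 to 0.09. Neither range overlaps, so these technical differences cannot be told apart from cell type here.

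The largest rises in normal platelets were those of MLH3, a DNA mismatch repair gene (77.7-fold), ABLIM3 (57.5-fold), BEX3 (54.9-fold), the histone genes H2BC12L, H2BC5 and H2BC12 (49.5-, 41.8- and 38.2-fold), LCN2 (46.8-fold), EMC3 (46.6-fold) and RGS10, a regulator of G protein signalling (39.8-fold). Histone genes of 1 family share much sequence and may be read by each other's probe sets. The largest falls were those of NFKBIA, the inhibitor of NF-kappa-B (124-fold lower), DUSP1 (94.3-fold), CXCL8 (88.8-fold), NOTCH2NLA (61.1-fold), DDX3X (60.4-fold), LEF1 (53.9-fold), LYZ (50.1-fold), SGK1 (43.7-fold) and CD14 (43.5-fold). The size of such falls depended on the settings. Over 21 alternatives the log2 difference ran from -7.46 to -5.27 for CXCL8 and from -6.36 to -4.32 for DDX3X. The LEF1 value came from the brightest of 3 probe sets, and 1 of them had the opposite sign. Without any 1 of the leukocyte samples its log2 difference ran between 0.47 and 1.06, with the opposite sign, and the call was lost.

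By gene group, 25 of 33 alpha granule and secreted protein genes rose in normal platelets and 1 fell (26 and 1 adjusted over the list alone), with PPBP 18.2-fold and CLU 20.4-fold higher (camera adjusted p = 8.48e-07, and adjusted p = 0.125 with an estimated correlation). In the cytoskeleton list 22 of 30 rose and 1 fell, by both adjustments, including MYLK (27.5-fold) and CTTN (22.2-fold), with camera adjusted p = 1.45e-06 and adjusted p = 0.297 with an estimated correlation. Among adhesion receptors 12 of 20 rose and 3 fell, by both adjustments, with GP9 17.1-fold and CLEC1B 19.5-fold higher (camera adjusted p = 0.0105, and adjusted p = 0.335 with an estimated correlation). Of 24 erythroid markers 18 rose and 2 fell, by both adjustments, with GMPR 14.6-fold higher (camera adjusted p = 0.000122, and adjusted p = 0.137 with an estimated correlation). Of 20 monocyte markers 18 fell and none rose, by both adjustments, with VCAN 29.4-fold lower (camera adjusted p = 1.28e-07, and adjusted p = 0.137 with an estimated correlation). Of 25 T cell markers 19 fell and 1 rose, by both adjustments, with LCK 35.6-fold lower (camera adjusted p = 1.45e-06, and adjusted p = 0.137 with an estimated correlation). Among immediate early and stress genes 22 of 29 fell and 4 rose, by both adjustments, with JUNB 41.2-fold lower (camera adjusted p = 1.45e-06, and adjusted p = 0.137 with an estimated correlation). In the proteasome list 27 of 36 fell and 1 rose (28 and 1 adjusted over the list alone), with PSMA3 14.6-fold lower (camera adjusted p = 8.48e-07, and adjusted p = 0.0943 with an estimated correlation). Of 52 ribosomal protein genes 38 fell and 1 rose (43 and 1 adjusted over the list alone, camera adjusted p = 6.69e-07, and adjusted p = 0.389 with an estimated correlation). Of 20 neutrophil markers 10 fell and 4 rose, by both adjustments (camera adjusted p = 0.075), with CXCR1 11.1-fold higher in normal platelets. Of 12 neutrophil precursor granule genes 2 fell and 3 rose, by both adjustments (camera adjusted p = 0.203), with LCN2 and CEACAM6 (5.50-fold) among those higher. Across all lists 17 of 25 passed with the preset correlation and 0 with an estimated one, where 8 had an unadjusted p under 0.05 and 23 passed by fry.

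The third comparison sets ET platelets against the same leukocyte samples. It gave 5163 of 8993 genes (57.4%) past the threshold by limma, 2327 higher and 2836 lower in ET platelets. The groups did not overlap in 1918 and 2509 of these (chance gives 2.38% for both directions together). Centring each array on its median turned the split to 3465 higher and 2138 lower, and quantile normalization to 2747 and 2378. Of 30 cytoskeleton genes 27 rose and 1 fell, by both adjustments, with camera adjusted p = 8.49e-12 (0.0252 with an estimated correlation). Of 35 alpha granule genes 30 rose and 1 fell, by both adjustments (adjusted p = 9.72e-11, and 0.0198 with an estimated correlation). Among 21 adhesion receptors 18 rose and 1 fell (19 and 1 adjusted over the list alone, adjusted p = 2.42e-08, and 0.0312 with an estimated correlation). Of 25 T cell markers 24 fell and 1 rose, and of 20 monocyte markers 19 fell and none rose, by both adjustments (adjusted p = 7.8e-10 and 1.12e-10, and 0.0198 and 0.0453 with an estimated correlation). Of 52 ribosomal protein genes 50 fell and none rose (51 and 1 adjusted over the list alone, adjusted p = 1.42e-12, and adjusted p = 0.19 with an estimated correlation). In total 18 of 25 lists passed with the preset correlation and 10 with an estimated one. The comparisons with leukocytes share the leukocyte samples, so their lists are not independent of each other.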

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

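The search for single samples apart from their group was set before the data were examined, and the test of probe sets without a single gene symbol uses the same threshold as the main comparison. In 305 sets of 5 or 6 values from 1 platelet group, 24 had a highest or lowest sample whose gap to its nearest neighbour took an unusually large share of the whole range. Chance gives about 1 in 20, or 15.3 of 305, so most of these may be chance, and none was left out of the main tests for it; leaving out the samples that stand apart gave 341 genes between ET and normal platelets.

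In ET platelets a single sample lay above the others for CD52 (gap 0.709 of the range), CST7 (0.697), HLA-DPB1 (0.642), TAL1 (0.677) and the mean of the neutrophil markers (0.703). A single sample lay below for MCM4 (0.647), PF4 (0.680) and PPBP (0.741). The log2 level of CST7 reached 15.6 in its highest sample. PF4 and PPBP stood at 14.5 and 14.1 in the lowest sample against 16.5 and 16.4 in the next. Both low values came from the ET array whose brightest probe set read 27187, where the other ET arrays reached at least 104445. Its 10 brightest probe sets held 2.34% of the summed intensity, close to the leukocyte arrays. Leaving this array out gave 465 genes between ET and normal platelets.

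In normal platelets a single sample lay below the others for CD79B (0.776), CD86 (0.904), FCGR2C (0.754), HSD17B11 (0.755), LAPTM4B (0.849), CD8B (0.752), GNLY (0.807), RRM2 (0.726) and the hybridization control level (0.830). A single sample lay above for EIF3J (0.846), ITGB3 (0.712), LCK (0.785), LEF1 (0.884), NKG7 (0.795), PSMC6 (0.712) and the mean of the erythroid markers (0.858). For ITGB3 the highest sample had a log2 level of 14.5 and the next 11.7, so the overlap of the groups for this gene rests on 1 normal sample. Apart from PF4 and PPBP in ET platelets, whether it was the same sample from gene to gene was not examined.

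Probe sets with several gene symbols or none belong to no comparison of the report. Of 1631 such probe sets bright enough to test, 212 differed between ET and normal platelets by limma, 97 higher and 115 lower in ET platelets.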

How the results depend on the processing

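The hybridization control level as covariate or block, the 3' to 5' ratio and the samples that stand apart were chosen after the data were seen. For ET against normal platelets the 910 genes became 1399 with array weights and 1431 with all 14 samples in one fit. They became 341 without the samples that stand apart (320 of them shared), 46 with the control level as a block (44 shared) and 19 with it as a covariate (18 shared). The joint fit left the median log2 difference of all genes at -0.30, while array weights moved it to -0.35. Why these counts, and the one without the samples that stand apart, moved was not tested. For the control level the differences shrank and their errors grew. Leaving out 1 sample gave 447 to 1362 genes. The counts were 600 and 465 without either of 2 ET samples, and 447 and 600 without either of 2 normal samples. The other settings gave counts within 1.5 times the main one, as did all settings tried for both comparisons with leukocytes. There the control level and the 3' to 5' ratio were not tried as covariates, so robustness to them is not shown. Lists past the threshold numbered 0, 0 and 10 with an estimated correlation, against 9, 17 and 18. By fry they numbered 8, 23 and 21, and for ET against normal platelets 5 of the 8 were among the 9. Pan-leukocyte markers differed by -0.56 with a pseudocount of 8 (exact p = 0.0476), and by -0.64 to -0.35 without single samples. Monocyte markers ran from -0.70 to -0.43 and B cell markers from -0.66 to -0.46, with exact p above 0.05 in 7 and 8 of 11 runs, and with quantile normalization they differed by -0.33 and -0.35. Without single samples LEF1 in normal platelets against leukocytes ran from -5.96 to 1.06. It turned to 0.79, 1.06 and 0.47 without 1 or another of the leukocyte samples, where the cause was not tested beyond the different probe set that stands for the gene. Of the named genes' other runs in ET against normal platelets, 1417 gave the same outcome, be it a call or no call, 247 lost a call and 25 gained one, and without single samples the numbers were 968, 123 and 16. The letters A to C occur in normal platelets and leukocytes, but no label says that they mark shared donors, and whether samples of 1 letter vary together was not tested, to avoid matching people's samples. With the letter as a replicate block 5958 genes passed against 5718. Dim genes are limited by signal over background, since the added constant of 32 compresses differences below it.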

Other observations

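The tests of leukocyte carry-over on the markers far higher in leukocytes, on the neutrophil markers and for the mix of the leukocyte samples, the covariates and the splits by control level and 3' to 5' ratio were chosen after the data were seen, and the other tests before. Several gene lists not described so far held members past the threshold while the list was not. As 11.8% of all genes tested passed, a few such members per list are no sign of a change in the list. Of 29 interferon-induced genes 3 rose in ET platelets and 1 fell, by adjustment over all genes and adjusted over the list alone. IFITM3, a membrane protein that restricts virus entry, was 7.50-fold higher (log2 difference 2.91 ± 0.59 SE, n = 6 and 5, limma adjusted p = 0.00234), IFITM2 3.47-fold and IFI6 3.21-fold higher, while the list did not pass (camera adjusted p = 0.666). Of 14 JAK-STAT target genes 2 rose and 2 fell, by both adjustments (camera adjusted p = 0.543). SOCS2 was 5.31-fold higher and the kinase gene PIM1 2.79-fold higher (a call lost in 9 of 26 alternatives), whereas SOCS3 was 3.34-fold lower. In eicosanoid synthesis 2 of 15 rose and 1 fell, by both adjustments (camera adjusted p = 0.198), with PTGES3 3.87-fold higher, HPGD, which degrades prostaglandins, 2.79-fold higher (a call lost in 15 of 28 alternatives) and ALOX5, the lipoxygenase of leukotriene synthesis, 3.07-fold lower (lost in 9 of 28).

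In the BCL2 family and caspases 1 of 23 rose and 2 fell, by both adjustments (camera adjusted p = 0.857), with BCL2, an inhibitor of apoptosis, 3.78-fold and CASP10 4.67-fold lower and CASP4 2.91-fold higher, the last a call lost in 14 of 28 alternatives. Of 29 translation factors 1 rose, EIF3J at 5.03-fold higher (camera adjusted p = 0.376, and 1 adjusted over the list alone). Of 22 immediate early and stress genes 2 fell, GADD45B (3.35-fold) and IL1B (2.99-fold), by both adjustments (camera adjusted p = 0.385), and these calls were lost in 6 and 15 of 27 alternatives. Of 19 genes of dividing cells 1 rose, MCM6 at 2.63-fold higher (lost in 13 of 28 alternatives), and 0 did when adjusted over the list alone (camera adjusted p = 0.75). The median and the mean difference had opposite signs in the lists of alpha granule proteins, JAK-STAT targets, translation factors and dividing cells, and camera, which compares a list with the other genes, placed the interferon-induced, BCL2 and NK lists upward although their medians were below 0.

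Chance assignment of samples was tested by refitting other splits. For ET against normal platelets 1 of 100 splits examined, of 462 possible, gave as many genes as the real one, namely the real split itself with 910. The highest other gave 876, in a split put among the 100 on purpose, the rest being drawn at random. Of the other splits 7 gave any gene, this one included. A chance assignment is thus unlikely to give 910 genes, which does not tell disease from a technical division of the samples. The split with 876 genes was the one of the 6 platelet samples with the lowest hybridization control level against the other 5. It exchanges 1 ET and 1 normal sample, and 409 of its genes were shared with the real split, all in the same direction. With this division as a block 46 genes passed. Given the group, 0 of 7722 genes were associated with the control level by limma (987 at an unadjusted p under 0.05). Given the control level, 19 differed between the groups (1035 at an unadjusted p under 0.05), so the unadjusted counts were close. The split by 3' to 5' ratio gave 0 genes by limma (462 at an unadjusted p under 0.05). For normal platelets against leukocytes 1 of 56 splits gave as many as the real 5718, with 1 gene as the highest other. For ET platelets against leukocytes 1 of 84 gave as many as the real 5163, with 0 as the highest other. A chance assignment is therefore unlikely to give either count. Splits that mix platelets and leukocytes widen the spread, so their low counts add little to that.

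The opposite change of HSD17B3 and HSD17B12 was weighed against array scaling and RNA integrity. With the hybridization control level as a covariate the difference of HSD17B12 was 2.69 ± 0.54 SE and that of HSD17B3 -3.18 ± 0.63 SE, and with the 3' to 5' ratio they were 3.28 ± 0.49 and -2.93 ± 0.53 SE. All stayed above 2 standard errors, which argues against a linear trend with either measure as the whole cause. As the control level goes partly with the group (squared correlation 0.36), array scaling itself is not excluded. Over 28 alternatives the adjusted p ran from 3.2e-06 to 0.0361 for HSD17B12 and from 6.15e-05 to 0.0333 for HSD17B3. As a hypothesis, found and tested on the same samples, the switch between these genes may belong to ET platelets, while treatment and other differences between the people sampled were not tested.

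The higher mean level of the adhesion receptor genes was weighed in the same way. The mean log2 difference of the 21 genes was 1.18 ± 0.24 SE, and it was 1.09 ± 0.23 with the 3' to 5' ratio and 0.79 ± 0.22 with the hybridization control level as a covariate. Both lie above 2 standard errors, so a linear trend with either measure does not account for the whole rise. As the control level goes partly with the group (squared correlation 0.36), array scaling itself is not excluded. Under the control level the calls of CD36, PECAM1, SELP and ITGB3 ended as the differences shrank and the errors grew. That of ITGA2B ended as its error grew. Part of the rise may therefore follow the control level, and the remainder may be biological, which is a hypothesis.

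Leukocyte markers were lower in ET platelets for 87 of 105 genes. Their median log2 difference of -0.67 lay at percentile 0.020 of 10000 random lists of equally bright genes. The random genes were drawn singly, while markers vary together (estimated correlation 0.089 for neutrophil and 0.112 for T cell markers). The control level was not tried as a covariate on this median. The markers thus fell more than equally bright genes drawn singly, but array scaling is not excluded. The markers' median drop was 9.48% of their leukocyte level (95% interval 7.18 to 15.0). Fewer carried-over leukocytes in the mix of the leukocyte samples could not lower them beyond the share of such RNA in normal platelet samples. The genes brightest in leukocytes allow 3.61% for it, and the drop lay above that. However, each marker was read by its probe set brightest in platelets, and the bound by probe sets brightest over all samples. Such a choice can lower a marker's leukocyte level and raise its drop. LEF1, for example, read 255 in normal platelets and 78.6 in leukocytes this way, against the direction given above. The drop therefore does not decide on cells in that mix. That bound, set before the data were examined for carry-over of any kind, takes the profile of these leukocyte samples for that of the carried-over cells and does not hold for another mix. Of 23 neutrophil and precursor markers 14 were brighter in normal platelets than in the leukocyte samples. Among them were CXCR1 at 393 against 5.53 and MMP25 at 1840 against 181, while S100A8 and S100A9 were brighter in the leukocyte samples. Some B and NK cell markers were also brighter in normal platelets, such as PAX5, BLK and NCR1 at 154, 149 and 152 against 20.8, 54.3 and 43.5. These values lay near the normal platelet arrays' medians of 58.6 to 136.4. They do not decide whether the excess is particular to neutrophils. Whether the leukocyte samples held few neutrophils was not tested. Fewer carried-over cells, in the mix of the leukocyte samples or another, therefore cannot be told apart from a change in platelets. For the 25 markers at least 8-fold higher in leukocytes than in normal platelets the median drop was 2.86% (95% interval 1.49 to 4.14). Of these, 18 were lower in ET platelets and 7 higher, such as CD37 at 932 against 261 and CYBA at 499 against 180, a rise that fewer carried-over cells alone would not give. As this choice caps the drop at 12.5%, carry-over cannot be told apart from a change in platelets for the lower ones either.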
